A study of Caenorhabditis elegans with 4 samples.

How the data were processed

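Whole-worm RNA of wild-type C. elegans on 2 diets was sequenced from 4 libraries, 2 per diet, as named by the labels. Per the labels' protocols, poly(A) RNA was isolated and libraries were made with a stranded total RNA kit. The deposited values are raw counts per gene, 1 file per library, with 46904 genes each. Per the submitters' processing notes, the tools included Trim Galore 0.6.5, Trimmomatic 0.39, cutadapt 2.7, STAR 2.7.2b and featureCounts 1.6.4, on the builds ce11 and WBcel235. Their roles, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so reads of overlapping, antisense and near-identical genes cannot be told apart with certainty. Total counts ranged from 34719633 to 47116429 per library, and 0 entries named no gene. Gene names and coordinates were those of the files, and 46817 of the gene identifiers were found in Ensembl release 115. No sequence of the genome was used here, and GC content was not analysed.

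Groups and replicate numbers came from the titles. Nothing says that replicates came from separate cultures, so p-values measure the spread between these samples alone, which may be technical. The test, lists, alternatives and rule for naming genes were fixed before the data were examined. Genes kept by filterByExpr (16161) were tested with the edgeR 4.0.16 quasi-likelihood test after TMM scaling, with diet as the sole term and Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values are scaled by TMM, and log2 CPM used a prior count of 2. Log2 fold changes are L. kimchii minus OP50. The common biological coefficient of variation was 0.159, with 2 residual degrees of freedom. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run beside it, in R 4.3.3. DESeq2 gave no adjusted p for 1236 of the genes tested, and these stayed without a value. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

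The 42 gene lists, fixed in advance from textbook functions, were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, and again with an estimated correlation. The latter test has the 2 residual degrees of freedom alone, so that few sets could pass it. Classes of gene symbols with at least 10 tested members, and Gene Ontology terms given in the files with 10 to 500 tested genes, were tested in the same way. The lists hold 2075 genes, 53 of them in more than 1 list, and 8 of the names given matched no gene. Members were also adjusted over the list alone. Named genes were the 5 with the smallest p in each direction, since 0 passed edgeR, 15 fixed genes, and insulin-like peptide genes with an unadjusted p under 0.05. Another 32 were named after their values were seen, because they passed when adjusted over the list alone.

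The fit was tested on simulated data, 3 sets with 200 changed genes each, drawn with the means, dispersions and library sizes of this comparison (15938 genes tested). It recovered 21.3% of 1.5-fold, 62.7% of 2-fold, 97.3% of 4-fold and 99.3% of 8-fold changes, and 10.2% of its calls were unchanged genes. The changed genes were drawn from those with a mean of at least 1 CPM. A list raised 1.3-fold had an unadjusted camera p under 0.05 in 3 of 3 sets, whereas the real lists were called on adjusted p. At most 1 list that was not raised passed an adjusted p of 0.05 in a set. The simulated genes varied independently and no simulated library stood apart, unlike in these data. The shares recovered therefore need not hold for the real fit, nor the list result for lists of correlated genes. Alternatives were other scalings, filters, tools and thresholds, thinning to the smallest library, the replicate number as a block, leaving out mitochondrial and ribosomal RNA genes, and leaving out each library. Added after the data were seen were robust dispersions, an adjusted p under 0.1, the Gene Ontology terms, and a covariate made of the germ line minus neuronal mean deviation of each library. The 4 libraries form 3 groupings into pairs, too few for a share under 0.05.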

Results

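The data were gene counts from whole wild-type hermaphrodites of Caenorhabditis elegans, Bristol strain N2. The worms were 3 days old at the start and were kept for 5 days on plates spread either with Escherichia coli OP50, the usual laboratory food, or with OP50 mixed with Lactococcus kimchii, a lactic acid bacterium. Each diet had 2 libraries, each made from poly(A) RNA of about 200 worms. The files held 34719633 and 40940005 counts for OP50 replicates 1 and 2, and 43474207 and 47116429 counts for the L. kimchii replicates 1 and 2. Protein-coding genes took 99.2% of the counts in both OP50 libraries and 99.1% in both L. kimchii libraries. All pairs of libraries differed by more than counting noise, so no pair looked like a single library deposited again, and the 4 were counted as the labels give them. The OP50 replicate 1 library stood apart: the leading principal component, which held 58.4% of the variance, placed it at -48.9 and the other libraries between 11.3 and 24.5. The SD of the log2 difference between libraries was 0.54 within OP50 and 0.33 within the L. kimchii diet. Relative to OP50 replicate 1, OP50 replicate 2 had a median log2 difference of -0.36 over the oocyte and germ line list and 0.48 over the neuronal list, while the medians between the diets were 0.00 and 0.02.

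The comparison asked which genes were regulated by feeding with L. kimchii. The gene with the smallest p was hrg-7, which encodes a secreted protein of heme signalling between tissues, at 70.7 ± 1.61 CPM on OP50 and 245 ± 47.7 CPM with L. kimchii (SD, n = 2 each). Other transcripts with higher values were ZK813.2, the cuticle collagen gene col-176, Y41C4A.32 and F55B11.2. The smallest p values among lower genes belonged to argk-1, an arginine kinase gene, nspe-1, F57F4.4, the collagen gene col-39 and C32H11.9. None of these 10 genes passed the edgeR test over all genes, and they are described here by their values. DESeq2 passed 7 of them, the exceptions being F57F4.4, col-39 and C32H11.9.

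For hrg-7 (WBGene00007605, WBcel235 chromosome V, 12742041 to 12744207) the log2 fold change was 1.80 (SE 0.15), with an edgeR adjusted p of 0.0537 and a DESeq2 adjusted p of 1.93e-17. The values of ZK813.2 (WBGene00022821, chromosome X, 3443782 to 3444420) were 88.9 ± 1.59 CPM on OP50 and 205 ± 6.58 CPM with L. kimchii (SD, n = 2 each), a log2 fold change of 1.21 (SE 0.11). Those of col-176 (WBGene00000749, chromosome X, 10077597 to 10078602) were 4.72 ± 0.194 and 18.1 ± 1.43 CPM, a log2 fold change of 1.94 (SE 0.19). The log2 fold change of Y41C4A.32 (WBGene00270321, chromosome III, 11721706 to 11723602) was 2.57 (SE 0.26). The means of F55B11.2 (WBGene00010084, chromosome IV, 14422268 to 14423294) were 55.6 ± 0.794 and 119.1 ± 7.46 CPM. In the other direction, argk-1 (WBGene00009706, chromosome V, 16103894 to 16105950) had 11.9 ± 5.09 CPM on OP50 and 3.63 ± 0.709 CPM with L. kimchii, a log2 fold change of -1.71 (SE 0.33). The log2 fold changes of nspe-1, F57F4.4, col-39 and C32H11.9 were -1.42 (SE 0.28), -0.54 (SE 0.11), -0.55 (SE 0.11) and -3.26 (SE 0.68), and C32H11.9 lay below 1 CPM in all 4 libraries.

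Of 16161 genes tested with the edgeR quasi-likelihood test, 0 passed an adjusted p of 0.05. An unadjusted p under 0.05 was found for 940 genes, 582 higher and 358 lower with L. kimchii, where 808 would come by chance. The limma-voom test passed 0 genes, with 987 at an unadjusted p under 0.05. DESeq2 passed 137 genes, 106 higher and 31 lower, and all 137 had the same sign and an unadjusted p under 0.05 in edgeR. Both L. kimchii libraries lay above or below both OP50 libraries for 33.5% of the genes, where chance gives 33.3%. The other groupings of the 4 libraries into pairs gave 1006 genes (replicate 1 libraries against replicate 2 libraries) and 211 genes at an unadjusted p under 0.05 with edgeR, the former more than the 940 by diet. They gave 0 and 0 genes past the threshold with edgeR and 0 and 1 with DESeq2. With no filter on low counts edgeR passed 399 genes. The edgeR count was 202 without OP50 replicate 1, 797 without OP50 replicate 2, 56 without L. kimchii replicate 1 and 43 without L. kimchii replicate 2, in fits where the lone library of a diet was assumed to vary like the others. Of the 137 DESeq2 genes, these fits passed 81, 120, 30 and 22.

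Genes named whatever their result included regulators and reporters of stress, immunity and metabolism, and 0 of the 15 passed the edgeR test, while sod-3 alone passed DESeq2 (adjusted p = 0.0499). The gene of the mitochondrial superoxide dismutase sod-3 had a log2 fold change of 1.21 (SE 0.34), and the lysozyme genes lys-7 and ilys-3 had values of 0.36 (SE 0.15) and 1.28 (SE 0.68). Means for the stearoyl-CoA desaturase gene fat-7 were 7.24 ± 3.13 CPM on OP50 and 19.01 ± 9.25 CPM with L. kimchii, and for the C-type lectin gene clec-60 1.76 ± 1.502 and 3.82 ± 0.733 CPM (SD, n = 2 each). Values for the insulin receptor gene daf-2 (-0.03, SE 0.13), the FOXO factor gene daf-16 (0.21, SE 0.15), skn-1 (-0.02, SE 0.11) and the p38 kinase gene pmk-1 (0.03, SE 0.15) lay within 2 standard errors of 0. The same held for gst-4 (-0.27, SE 0.24), acdh-1 (-0.23, SE 0.16), vit-2 (0.15, SE 0.13) and nlp-29 (0.21, SE 0.16). The small heat shock gene hsp-16.2 was at -0.51 (SE 0.16) and the acyl-CoA synthetase gene acs-2 at -0.31 (SE 0.11). The values of daf-2 without OP50 replicate 2 (0.13), and of gst-4 (0.12) and pmk-1 (-0.10) without OP50 replicate 1, had the opposite sign. Without OP50 replicate 2 the values of daf-16 (0.42), sod-3 (1.81), gst-4 (-0.600), ilys-3 (3.09) and clec-60 (2.45) passed edgeR, and without L. kimchii replicate 2 those of ilys-3 (1.69) and fat-7 (1.82), while 0 of the 15 passed without OP50 replicate 1 or without L. kimchii replicate 1. Values nearer 0 came without OP50 replicate 1 for daf-16 (0.0067), sod-3 (0.78), ilys-3 (0.49), clec-60 (0.41) and acdh-1 (-0.020), and without L. kimchii replicate 1 for fat-7 (0.78), ilys-3 (0.70) and lys-7 (0.14). Among insulin-like peptide genes, ins-20, ins-7 and ins-11 had an unadjusted p under 0.05, and none passed the edgeR test over all genes, while ins-20 passed DESeq2 (adjusted p = 0.0348) and edgeR without OP50 replicate 2 (adjusted p = 0.017). Their means on OP50 were 0.571, 1.07 and 0.26 CPM, and with L. kimchii 2.34, 1.95 and 0.597 CPM.

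Gene lists fixed beforehand were compared between the diets as groups. The metal-handling list was higher with L. kimchii, and its members with the smallest p were genes of heme handling. The intracellular pathogen response list, most of it pals genes that are induced by microsporidia and viruses, was higher as well. The list named for immune targets of the p38 kinase PMK-1 was lower, with 18 of 18 members below their OP50 value. Control of each member by PMK-1 was not tested here. Genes of the vitellogenins, the yolk proteins made in the intestine, were lower for 5 of 6 members. With camera, 17 of 41 lists passed, 8 higher and 9 lower. None of the 17 passed with an estimated correlation, the smallest adjusted p then being 0.498. That test rested on 2 residual degrees of freedom, which made it hard to pass at any correlation. The estimated correlation of the metal-handling list was 0.008, below the preset 0.01, yet its camera p went from 7.87e-10 to 0.0247. Estimates were far above the preset for FMRFamide-like neuropeptides (0.929), body-wall muscle (0.559), PMK-1 targets (0.466) and vitellogenins (0.322). They were below it for some others, such as fatty acid synthesis and desaturation (-0.048). These losses cannot tell whether the calls came from correlation between genes. Other groupings of the 4 libraries passed 16 and 12 lists, and 10 of the 17 passed in the grouping by diet alone.

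In the metal-handling list (24 genes tested, median log2 fold change 0.30, camera adjusted p = 1.07e-08, adjusted p = 0.498 with an estimated correlation) 0 genes passed over all genes tested by edgeR, 5 had an unadjusted p under 0.05, and DESeq2 passed 3. The same 5 passed when adjusted over the list alone, all higher: hrg-7, hrg-1, hrg-2, mrp-5 and hrg-3, named here because of that result. The endolysosomal heme transporter gene hrg-1 (WBGene00019830, chromosome X, 4008058 to 4016185) had 12.76 ± 1.65 CPM on OP50 and 25.4 ± 2.59 CPM with L. kimchii (SD, n = 2 each), a log2 fold change of 0.99 (SE 0.18). The hypodermal gene hrg-2 (WBGene00010473, chromosome V, 12409369 to 12410513) had 4.70 ± 0.829 and 11.3 ± 2.95 CPM, a log2 fold change of 1.26 (SE 0.26). For the heme exporter gene mrp-5 (WBGene00003411, chromosome X, 14938502 to 14946317) the means were 99.2 ± 1.38 and 142 ± 3.85 CPM and the log2 fold change 0.52 (SE 0.11). The gene hrg-3 (WBGene00010256, chromosome V, 9756485 to 9757019), whose product carries maternal heme to embryos, stayed below 1 CPM in all libraries, with a log2 fold change of 2.38 (SE 0.50). Exons of F58E6.11 on the opposite strand overlap hrg-3 and held 647 counts against 81 for hrg-3, so that reads of these genes could not be told apart with certainty. The 7 tested genes of heme handling had a median log2 fold change of 0.99, against 0.19 for the 17 other metal-handling genes, a division made after the values were seen. The list median was 0.14 without OP50 replicate 1.

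**Figure D1:**
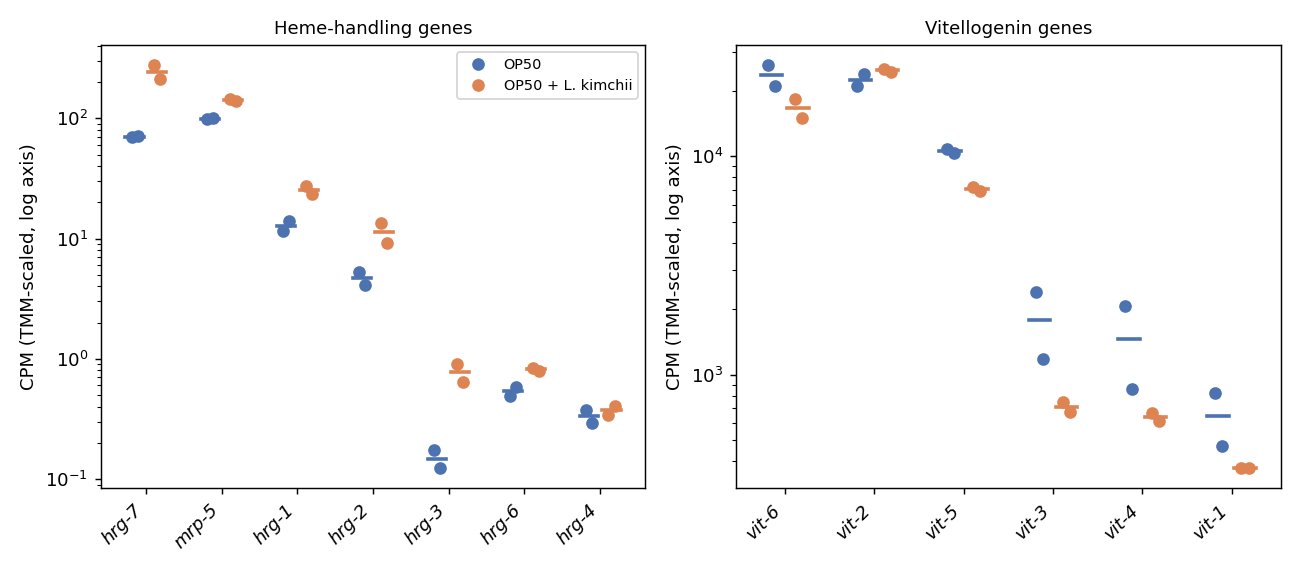
Normalised CPM (log axis) of 7 heme-handling genes (left) and the 6 vitellogenin genes (right) in each library, with dots for the 2 libraries of each diet and a line at their mean. For hrg-7 the OP50 libraries lie at 69.5 and 71.8 CPM and the L. kimchii libraries at 279 and 212 CPM, and for vit-3 OP50 replicate 1 at 2380 CPM lies above replicate 2 at 1179 CPM.

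In the intracellular pathogen response list (23 genes, median 0.77, camera adjusted p = 3.99e-10, adjusted p = 0.498 with an estimated correlation) 22 genes had higher values, 10 of them with an unadjusted p under 0.05, and 1 lower. Of these, edgeR passed 0 over all genes, DESeq2 passed 2, and pals-26 (log2 fold change 1.43, SE 0.27) passed when adjusted over the list alone. Reads of pals genes can be shared between near-identical copies. The list median was 0.46 without OP50 replicate 1, over the 26 genes tested there, and 0.44 over the 8 genes with at least 5 CPM. The list of PMK-1 targets (18 genes, median -0.63, camera adjusted p = 3.99e-10, adjusted p = 0.498 with an estimated correlation) held 8 lower genes at an unadjusted p under 0.05, while edgeR and DESeq2 each passed 0. When adjusted over the list alone, irg-5, T24B8.5, irg-2, clec-85, dod-24 and irg-3 passed, all lower, with log2 fold changes from -1.78 for irg-5 to -0.63 for irg-3. The values were highest in OP50 replicate 1 for all of these named genes, though narrowly for irg-3 (8.99 CPM, against 8.55 in OP50 replicate 2). T24B8.5 had 32.4 CPM in OP50 replicate 1, 11.9 in OP50 replicate 2, and 6.91 and 8.79 with L. kimchii. The list median was -0.21 without OP50 replicate 1, and the list also passed in both other groupings of the libraries.

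Of the vitellogenin genes (median -0.69, camera adjusted p = 6.50e-08, adjusted p = 0.498 with an estimated correlation) edgeR passed 0 over all genes, with 5 lower at an unadjusted p under 0.05, and DESeq2 passed 2. When adjusted over the list alone, vit-5, vit-3, vit-4, vit-1 and vit-6 passed, all lower. The mean of vit-5 was 10577 ± 280.5 CPM on OP50 and 7081 ± 197 CPM with L. kimchii (SD, n = 2 each), a log2 fold change of -0.58 (SE 0.12). The log2 fold changes of vit-3, vit-4, vit-1 and vit-6 were -1.32 (SE 0.29), -1.18 (SE 0.34), -0.79 (SE 0.24) and -0.51 (SE 0.16). Reads of vit-3, vit-4 and vit-5, which are close copies, may have been divided between them. Such sharing was not measured for any vitellogenin gene, since no sequence was used here. The 6 genes together took 6.29% and 5.76% of the counts on OP50 and 5.29% and 4.78% with L. kimchii. The list median was -0.40 without OP50 replicate 1, and the list also passed in 1 other grouping.

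The cuticle collagen list (150 genes, median -0.22, camera adjusted p = 3.05e-08, adjusted p = 0.498 with an estimated correlation) had 118 lower and 32 higher members, with edgeR passing 0 over all genes and DESeq2 passing 14. When adjusted over the list alone, 6 passed as higher (col-176, col-103, col-98, col-142, col-141 and col-42) and 3 as lower (col-39, col-91 and col-12). Its median was -0.43 without L. kimchii replicate 1 and -0.12 without L. kimchii replicate 2, and it passed in both other groupings. In lipid metabolism, the list of fatty acid synthesis and desaturation (22 genes, median 0.17, camera adjusted p = 0.00111, adjusted p = 0.498 with an estimated correlation) and that of fat breakdown (40 genes, median 0.08, camera adjusted p = 0.0168, adjusted p = 0.498 with an estimated correlation) were higher. Passing when adjusted over the list alone were the delta-12 desaturase gene fat-2 (0.67, SE 0.14), acox-3 (0.69, SE 0.14) and the carnitine palmitoyltransferase genes cpt-3 (1.47, SE 0.30) and cpt-4 (-0.67, SE 0.14). The fat breakdown call was lost without L. kimchii replicate 1 (median 0.046, adjusted p = 0.073). Digestive proteases (21 genes, median 0.18, camera adjusted p = 0.00387, adjusted p = 0.498 with an estimated correlation) were higher, and the cathepsin B-like genes cpr-4 and cpr-8 passed when adjusted over the list alone. For cpr-4 the means were 399 ± 10.2 CPM on OP50 and 772 ± 56.2 CPM with L. kimchii (SD, n = 2 each), a log2 fold change of 0.95 (SE 0.12). The protease list median was 0.025 without L. kimchii replicate 1 and 0.021 over the 17 genes with at least 5 CPM.

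C-type lectins (133 genes, median 0.15, camera adjusted p = 0.00184, adjusted p = 0.55 with an estimated correlation) and antioxidant enzymes (26 genes, median 0.13, camera adjusted p = 0.0357, adjusted p = 0.498 with an estimated correlation) were higher. The lectin median was 0.34 without OP50 replicate 2 and 0.096 over the 52 genes with at least 5 CPM. On the lectin list OP50 replicate 2 lay above OP50 replicate 1 by a median of 0.215, more than the difference between the diets. The median deviation from the mean of the 4 libraries was -0.207 in OP50 replicate 1 and 0.026 in OP50 replicate 2. It was 0.075 and 0.116 in the L. kimchii libraries. The antioxidant call was lost without OP50 replicate 2 (median 0.16, adjusted p = 0.0756) and without L. kimchii replicate 1 (median 0.083, adjusted p = 0.153), and the median was 0.20 without L. kimchii replicate 2. FMRFamide-like neuropeptides were higher (30 genes, median 0.31, camera adjusted p = 4.46e-06, adjusted p = 0.689 with an estimated correlation). Their median was -0.012 without OP50 replicate 1, which ended the call (adjusted p = 0.78), 0.63 without OP50 replicate 2 and 0.11 without L. kimchii replicate 2, and the 2 OP50 libraries themselves differed by 0.70 on this list, which also passed in 1 other grouping. Lower lists included the mitochondrially encoded genes (12 of 12 lower, median -0.13, camera adjusted p = 0.0114, adjusted p = 0.55 with an estimated correlation), a call lost without L. kimchii replicate 1 (median -0.11, adjusted p = 0.133). Also lower were the cytosolic heat shock response (23 genes, median -0.10, camera adjusted p = 0.0168, adjusted p = 0.498 with an estimated correlation) and SKN-1 oxidative stress targets (22 genes, median -0.17, camera adjusted p = 0.0411, adjusted p = 0.498 with an estimated correlation). The heat shock median was -0.22 without OP50 replicate 1, and its call was lost without OP50 replicate 2 (median -0.16, adjusted p = 0.223) and over the 17 genes with at least 5 CPM (median -0.055, adjusted p = 0.0702). The SKN-1 call was lost without any 1 of the 4 libraries, with adjusted p from 0.0502 to 0.407. Its median was -0.084 without OP50 replicate 1, -0.21 without OP50 replicate 2, -0.22 without L. kimchii replicate 1 and -0.12 without L. kimchii replicate 2.

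Body-wall muscle genes (30 genes, median -0.11, camera adjusted p = 0.0116, adjusted p = 0.737 with an estimated correlation) and pharynx genes (24 genes, median -0.29, camera adjusted p = 0.0168, adjusted p = 0.689 with an estimated correlation) were lower, and both passed in every grouping of the libraries. Without OP50 replicate 2 their medians were 0.029 and 0.063, of the opposite sign. Without OP50 replicate 1 they were -0.28 and -0.44, and the pharynx median was -0.46 without L. kimchii replicate 1. The muscle call was also lost without L. kimchii replicate 1 (median -0.10, adjusted p = 0.142) and the pharynx call without L. kimchii replicate 2 (median -0.14, adjusted p = 0.0704). Embryonic patterning genes were lower (22 genes, median -0.12, camera adjusted p = 0.0357, adjusted p = 0.689 with an estimated correlation), a call lost without OP50 replicate 1 (median -0.080, adjusted p = 0.873) and without L. kimchii replicate 2 (median -0.18, adjusted p = 0.052). Their median was -0.25 without OP50 replicate 2 and -0.24 without L. kimchii replicate 1, and the list also passed in both other groupings.

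**Figure D2:**
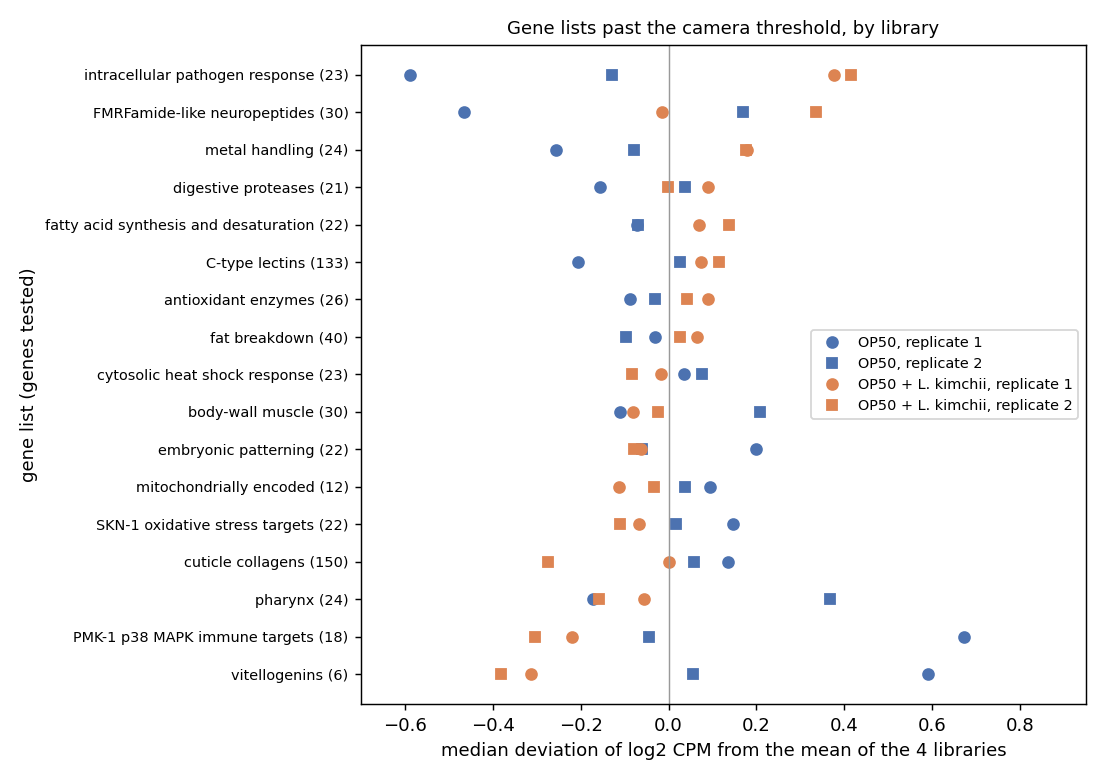
Median deviation of log2 CPM from the mean of the 4 libraries (horizontal axis) for the 17 gene lists past the camera threshold, with 1 symbol per library and the number of genes tested in brackets. The PMK-1 target and vitellogenin lists lie farthest to the right in OP50 replicate 1, and the intracellular pathogen response list has both L. kimchii libraries to the right of both OP50 libraries.

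The remaining 24 tested lists did not pass camera. Among lists of insulin signalling and ageing, the medians were 0.28 for insulin-like peptides (camera adjusted p = 0.0615), 0.01 for insulin/IGF-1 signalling, 0.16 for DAF-16 class I targets and -0.23 for DAF-16 class II targets. Among immune lists they were 0.11 for saposin-like proteins, 0.15 for lysozymes, 0.01 for antimicrobial peptides and 0.09 for the osmotic and wounding response. Within these lists spp-15 (0.62, SE 0.12) and the thaumatin-like gene thn-2 (1.49, SE 0.27) passed when adjusted over the list alone, as did gsto-1 (1.75, SE 0.24) among glutathione S-transferases (median 0.01). Exons of kle-2 on the opposite strand overlap gsto-1 and held 15143 counts against 1436 for gsto-1, and those of C48E7.6 overlap spp-15 and held 4375 counts against 8904, so that reads could not be told apart with certainty for either gene. Medians of 0.04 were found for cytochrome P450s, 0.05 for UDP-glycosyltransferases, -0.05 for the ER unfolded protein response, 0.07 for the mitochondrial unfolded protein response, 0.06 for the nuclear-encoded respiratory chain and 0.04 for cytosolic ribosomal proteins. Those of the proteasome, the neuronal list, the intestine list, the oocyte and germ line list, histones and the F-box and MATH/BTB proteins were 0.02, 0.02, -0.01, 0.00, 0.14 and 0.02. Autophagy and lysosome genes had a median of 0.08, the hypoxia and H2S response 0.00, and the vitamin B12, methionine cycle and propionate list 0.03. Camera and mean pointed down and the median up for UDP-glycosyltransferases and the vitamin B12 list, camera and mean pointed up and the median down for the hypoxia list, and for the germ line list the mean alone was above 0. The sperm list had 4 tested members, too few for the test.

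Classes of genes sharing a name were scanned in the same way. The nspc and pals classes, the latter largely the list above, were the highest, and collagen and fbxb genes were lower. Of 142 classes, 21 passed camera, 9 higher and 12 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.987. The limit of 2 residual degrees of freedom held for that test here too. Other groupings of the libraries passed 46 and 29 classes, more than the grouping by diet. The count was 28 without OP50 replicate 1, 30 without OP50 replicate 2, 26 without L. kimchii replicate 1 and 9 without L. kimchii replicate 2, with 11, 13, 18 and 9 of the 21 among them in the same direction. Only nspc and pals passed in all 4 of these fits.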

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

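Robust dispersions, the germ line and neuronal covariate and the adjusted p of 0.1 were chosen after the data were seen. The edgeR count of 0 genes (940 at an unadjusted p under 0.05) stayed 0 with RLE or upper-quartile scaling, at least 5 CPM, thinning, mitochondrial and ribosomal RNA genes left out, robust dispersions, limma-voom and a log2 fold change of at least 1. It was 399 with no filter on low counts (395 of them also tested with the filter), 137 with DESeq2, 5 at an adjusted p of 0.1 and 1296 with the covariate, and the cause was not tested. The covariate, made from these same libraries, left 1 residual degree of freedom. The common biological coefficient of variation was 0.079 with it, against 0.159 in the main fit. Leaving out 1 library gave 43 to 797 genes, with 1 residual degree of freedom. The replicate numbers were not shown to pair the libraries (correlation of same-numbered deviations 0.169 over 2 pairs), and with them as a replicate block 515 genes passed, including all 137 of DESeq2. The block fit also left 1 residual degree of freedom, with a common coefficient of variation of 0.138. Lists passing numbered 16 to 20 under scaling, filter, block and covariate settings, 13 to 23 without 1 library, and 0 with an estimated correlation. Classes numbered 14 to 25 under those settings, 9 to 30 without 1 library (9 to 18 of the 21 among them), and 0 with an estimated correlation. At least 5 CPM ended the SKN-1, heat shock and embryonic patterning calls, the block the SKN-1 call (adjusted p = 0.0612), and the covariate the SKN-1 (0.057) and embryonic patterning (0.0549) calls. Without OP50 replicate 2 the medians of body-wall muscle (0.029) and pharynx (0.063) and the value of daf-2 (0.13) reversed, and without OP50 replicate 1 gst-4 (0.12) and pmk-1 (-0.10). Over the fits without 1 library these 5 ran from -0.28 to 0.029, -0.46 to 0.063, -0.20 to 0.13, -0.60 to 0.12 and -0.10 to 0.15. For the 60 named genes, 627 values under alternatives kept their side of the threshold, 259 passed it and 3 reversed. Genes under 1 CPM, such as hrg-3 and C32H11.9, rest on few counts.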

Other observations

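Other gene classes past the camera threshold, none of which passed with an estimated correlation (smallest adjusted p = 0.987), included the nspc genes, named for nematode-specific peptides, with 16 of 16 higher and a median log2 fold change of 0.69. The chitinase-like chil genes had 21 of 22 higher with a median of 0.36, and the transthyretin-like ttr genes 34 of 50 higher with a median of 0.13, among them 4 that passed DESeq2. The ttr members with the smallest p, chosen after their values were seen, were ttr-34 at 1.36 (SE 0.23), ttr-45 at 0.72 (SE 0.13) and ttr-51 at 0.62 (SE 0.11). The fbxb class of F-box genes had 85 of 100 members lower (median -0.27), and 10 of 10 tested abu genes and 20 of 20 vha genes, which encode subunits of the vacuolar proton pump, were lower with medians of -0.39 and -0.11. The abu medians of L. kimchii replicate 1 (0.04 above the mean of the 4 libraries) and OP50 replicate 1 (0.03 above it) were close, and the L. kimchii replicates differed by -0.44. OP50 replicate 2 differed from OP50 replicate 1 by medians of 0.61 for nspc, 0.45 for chil and -0.45 for fbxb, close to or above the differences between the diets. Of 1091 Gene Ontology terms, 19 passed, 6 higher and 13 lower, and 0 with an estimated correlation (smallest adjusted p = 0.999), while the other groupings of the libraries passed 411 and 248. The count was 292 without OP50 replicate 1, 110 without OP50 replicate 2, 24 without L. kimchii replicate 1 and 11 without L. kimchii replicate 2, with 14, 11, 14 and 8 of the 19 among them. Only the lysosome, which was higher (89 genes, median 0.055, 5 passing DESeq2), and lipid transporter activity, which was lower (13 genes, median -0.15, 2 passing DESeq2), passed without each library in turn. Fatty acid metabolism (53 genes, median 0.095, 4 passing DESeq2) was higher, a call lost without OP50 replicate 2 and without L. kimchii replicate 1, and neuropeptide signalling (median 0.199) was higher, a call lost without OP50 replicate 1 and without L. kimchii replicate 2. The collagen trimer (146 genes, median -0.22) and cell adhesion (43 genes, median -0.104) were lower, calls lost without L. kimchii replicate 2 and without OP50 replicate 2, respectively.

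The tests that left out OP50 replicate 1 and the test of hrg-4 were chosen after the results they bear on had been seen, as was a gene-by-gene comparison given for some of them, which was added after the first outcome was known. Medians below are over genes tested in both fits. The standard errors of these medians and margins come from the spread between genes, taken as independent. They do not measure the spread between libraries.

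The heme-handling genes had a median log2 fold change of 0.99 (SE 0.37, 7 genes). Thinning every library to the smallest total left a median of 1.03. Thinning keeps each gene's expected share of the counts, so this value was bound to stay close and cannot decide on depth. Without OP50 replicate 1 the median was 0.85 (SE 0.40). The rule first written required a margin above 50 percent of the full value that exceeds this standard error. By that rule, this library's part cannot be told apart. The later gene-by-gene comparison gave a margin of 0.35 (SE 0.22). Its standard error treats genes of the same libraries as replicates, so that comparison cannot exclude this library's part. A lower heme supply from the mixed diet is a hypothesis that predicts a higher hrg-4, and its value of 0.16 (SE 0.46), at under 1 CPM, leaves this open. Both the diet and the departure of 1 control library thus may bear on this group.

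The PMK-1 targets (median -0.63) and the vitellogenins (median -0.69) were both highest in OP50 replicate 1. With the germ line and neuronal covariate the medians were -0.52 and -0.63, but its means of 0.02 on OP50 and -0.02 with L. kimchii were so close that it could hardly move a difference between the diets, and the part of that make-up is left open. Without OP50 replicate 1 the PMK-1 median was -0.21, under 50 percent of its full value, so that this library may account for much of the difference. For the vitellogenins it was -0.40 (SE 0.13), and the library and the diet cannot be told apart there, since the margin was smaller than its standard error under both comparisons.

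The intracellular pathogen response genes had a median of 0.77 (SE 0.12), and 0.70 after thinning, which, as above, cannot decide on depth. Without OP50 replicate 1 the median was 0.45 (SE 0.13). This leaves that library's part open, because only 1 control library remains and the margin was under its standard error. The later gene-by-gene margin was 0.12 (SE 0.10). Its standard error also treats genes of the same libraries as replicates, so that comparison cannot exclude this library's part. The 6 members outside the pals family had a median of 0.16 (SE 0.11), so reads shared between pals copies may contribute, and a response of the pals family alone also stays open. No sequence was used here to measure how many reads the copies share.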
